A study of Mus musculus with 24 samples.

How the data were processed

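RNA from T6E cells, a mouse T-cell acute lymphoblastic leukaemia line whose growth depends on Notch1, was measured on 24 arrays. The labels name 4 constructs carried by the cells and 2 treatments, which make 8 groups of 3 arrays. MigR1 is the empty vector. DNMAML is a dominant negative form of Mastermind-like, the coactivator of the Notch transcription complex. ICN1 is intracellular Notch1, which needs no cleavage by gamma-secretase to act. R1984A is an intracellular Notch1 that cannot dimerize, per the labels. Cells received DMSO or 1 uM compound E, a gamma-secretase inhibitor (GSI), for 6 hours, per the labels. The groups are named here by construct and treatment, such as ICN1-GSI.

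The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes, the authors used the R packages oligo and limma, with no version or step named. How background was corrected and how arrays were normalized and summarized is not given in the sources used here. The table holds 35556 probe sets with values from 1.28 to 13.47 on the log2 scale, and the medians of the 24 arrays lie between 3.90 and 4.18. The scale was read from that range. The deposited values were used without further scaling.

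Probe sets were named from the platform annotation of the Affymetrix Mouse Gene 1.0 ST array. Of the 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were unnamed in the table used here. Of those with 1 symbol, 21698 matched a RefSeq gene by gene identifier, and 0 symbols changed. For 999 genes with more than 1 probe set, the probe set with the highest mean over the 24 arrays was kept, which left 19938 genes. No filter on dim genes was applied. The RefSeq table of assembly GRCm38.p6 was used only for names and for which genes neighbour each other.

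Differences were estimated with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 24 arrays, so that the 8 groups share 1 estimate of the spread per gene. This gave 16 residual and 6.56 prior degrees of freedom. A gene was called when its two-sided moderated test had a Benjamini-Hochberg adjusted p under 0.05 over the 19938 genes. All p-values below are adjusted p-values of this limma fit, or of limma's camera for gene lists, unless stated. A log2 difference is given with its standard error (SE), and a group mean with its SD over 3 arrays. By chance alone, 996.9 genes would pass an unadjusted p of 0.05. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

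The 10 comparisons of groups and the 4 tests of whether the response to GSI differed between constructs were fixed before the data were examined, with the alternatives, 18 gene lists and the rule for genes named. The rule takes up to 10 genes with the largest rise and up to 10 with the largest fall in each of the 5 main comparisons, and up to 5 each way elsewhere. Such genes had to be called, with the 3 arrays of one group all above the 3 of the other, which 10% of unchanged genes do by chance. Clone names, small RNAs and antigen receptor segments were left out. Every measured Notch target of the list was tested and enters the counts given, but not each is named. From other lists up to 4 called members with the largest change are given as examples. Notch1, Maml1 and Rbpj were named as checks of the labels.

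The lists hold Notch targets, targets linked to paired Notch binding sites, targets taken to be independent of dimerization, Notch pathway components, Myc and ribosome biogenesis genes, G1/S genes, G2/M genes, cholesterol synthesis, amino acid stress, interferon response, p53 and apoptosis, quiescence, T-lineage genes and markers of B cells, myeloid cells, erythroid and megakaryocyte cells, natural killer and innate cells, and stroma or epithelium. Of the Notch targets, 28 were measured. Camera was run with a preset inter-gene correlation of 0.01 and adjusted over the 18 lists of a comparison, and again with an estimated correlation. A separate set, of genes lowered both by GSI and by DNMAML, was chosen from comparisons other than that of ICN1-GSI with R1984A-GSI, in the fit of all arrays, whose common spread estimate includes these 2 groups.

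The titles number the samples of each group from 1 to 3. Samples with the same number deviated together from their group means with correlations of at least 0.158 (GSI in MigR1 cells), 0.114 (DNMAML), 0.144 (ICN1 against MigR1 in DMSO), 0.194 (ICN1 against R1984A in DMSO), 0.168 (GSI in DNMAML cells) and 0.106 (the test of whether the GSI response differed between DNMAML and MigR1 cells). Each pair was thus above 0.1, and for these the fit with the replicate number as a block stands beside the result where it moves the count by over 1.5 times, as from 33 to 82 genes for GSI in MigR1 cells. For the other comparisons at least 1 pair was below 0.1, which does not show their samples to be unpaired. For ICN1-GSI against R1984A-GSI the correlations were 0.446, 0.058 and 0.447, with a mean of 0.317 against 0.264 for DNMAML. The counts of these comparisons with the block are given in the part on processing. Replicate 3 arrays had medians of 4.05 to 4.18, against 3.90 to 4.07 for replicates 1 and 2. The first principal component of the within-group deviations held 38.9% of their variance.

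The alternatives were the replicate block, every probe set, only genes above the median probe set, a second quantile normalization, an intensity trend with robust eBayes, array weights, only the groups compared, and each array left out in turn. Leaving out all replicate 3 arrays was added after the data were seen. The steps were tested on simulated data that took each gene's mean and within-group spread from these arrays and added independent normal noise. Unlike the real arrays, the simulated ones had no shared deviation of replicates and no correlation between genes. The shares below may therefore not hold for the real data. For ICN1-GSI against R1984A-GSI, 26.9% of genes changed by 0.5 on the log2 scale were called, 94.0% at 1 and 100% at 2, and 4.55% of the calls were unchanged genes. For GSI in MigR1 cells these shares were 28.4%, 82.1% and 100%, with 4.76% of calls unchanged. For the difference in GSI response between ICN1 and R1984A cells they were 2.99%, 68.7% and 97.0%, with 6.67%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.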

Results

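Gene expression was profiled in T6E leukaemia cells that carried the empty vector MigR1, DNMAML, ICN1 or R1984A, each after 6 hours in DMSO or in 1 uM compound E (GSI), with 3 arrays in each of 8 groups. The series title names paired binding sites of the Notch transcription complex, at which a pair of complexes can dimerize. GSI and DNMAML block the Notch signal at different steps, and ICN1 and R1984A supply it past the GSI block with and without dimerization. Arrays of the same group correlated with r of 0.982 to 0.994 across genes, which are not independent replicates.

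The Notch1 probe set was read first as a check of the labels. Its mean log2 value was 5.66 ± 0.06 in MigR1-GSI, 7.32 ± 0.07 in ICN1-GSI and 7.07 ± 0.08 in R1984A-GSI (SD, 3 arrays each). ICN1 cells thus stood above the empty vector by 1.65 (SE 0.13, adjusted p = 1.8e-08) and R1984A cells by 1.41 (SE 0.13, adjusted p = 4.3e-07). The constructs differed from each other by 0.25, with a 95% interval of -0.02 to 0.51 in GSI, and by 0.27 (0.01 to 0.53) in DMSO, neither called. Maml1 and Rbpj were called in none of the 10 group comparisons. Where the Notch1 and Maml1 probe sets lie relative to the transfected parts was not examined, so it is open whether these values read the constructs.

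In cells with the empty vector, GSI lowered known direct Notch targets. Nrarp, a feedback inhibitor of Notch, fell by 1.21 (SE 0.11, adjusted p = 1.5e-06) from 5.31 ± 0.16 to 4.09 ± 0.09. The latter lay within the range of the array medians, so the size may be uncertain. Hey1, a transcriptional repressor, fell by 1.00 (SE 0.11, adjusted p = 2.0e-05), and Myc, the growth regulator that Notch drives in this leukaemia, fell by 1.503 (SE 0.21, adjusted p = 7.0e-04). The largest fall among the genes named was that of Mfsd2a, a lysophospholipid transporter, which fell by 1.59 (SE 0.17, adjusted p = 2.0e-05). Serpinb8 (-1.296, SE 0.17), the protease gene Capn5 (-1.22, SE 0.16) and Deptor, an inhibitor of mTOR (-1.06, SE 0.15), also fell. The called rises were smaller, with Ccng2, a cyclin induced when growth signals drop, at 0.84 (SE 0.16, adjusted p = 0.034) and Atp6v0a1, a subunit of the vacuolar proton pump, at 0.69 (SE 0.12, adjusted p = 0.013). Ccr8, from 6.25 ± 0.29 to 7.75 ± 0.19, had the largest difference upward, at 1.499, and was not called (adjusted p = 0.23).

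Of the 28 measured Notch targets, 5 fell and 0 rose with GSI (Hey1, Dtx1, Nrarp, Il2ra and Myc), and 7 fell and 1 rose when adjusted over the list alone, with a camera p of 8.0e-10 and 3.9e-05 with an estimated correlation. Of the 5 paired-site targets 2 fell (camera adjusted p = 2.0e-10; 4.0e-05 with an estimated correlation), and so did both targets taken to be independent of dimerization, Hey1 and Il2ra (camera adjusted p = 3.3e-12; 4.0e-05). Notch1 itself was at -0.56 (SE 0.13, adjusted p = 0.11), and with the replicate block its adjusted p was 0.042. Of 55 Myc and ribosome biogenesis genes limma called 0, with 8 at an unadjusted p under 0.05 and 5 lower when adjusted over the list alone. That list's camera p of 2.3e-11 became an adjusted p = 0.21 with an estimated correlation. For 27 G2/M genes limma called 0, with 2 at an unadjusted p under 0.05, and the camera p of 6.3e-07 upward became an adjusted p = 0.29 with an estimated correlation. Among 30 T-lineage genes Runx1, a transcription factor of blood development, was the only one called, at -0.69 (SE 0.11, adjusted p = 0.0032), and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0080 upward; adjusted p = 0.28 with an estimated correlation).

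In all, GSI changed 33 genes in MigR1 cells, 6 higher and 27 lower, and 82 with the replicate block. At an unadjusted p under 0.05 in the limma fit there were 972 genes, below the 996.9 expected by chance. Leaving out MigR1-DMSO replicate 1, 2 or 3 gave 18, 15 and 18 genes, leaving out MigR1-GSI replicate 1, 2 or 3 gave 19, 21 and 16. Leaving out all replicate 3 arrays gave 17. With only the groups compared 4 genes were called, Nrarp, Mfsd2a and Dtx1 among them, and Hey1 (0.092), Deptor (0.092), Serpinb8 (0.17), Il2ra (0.19), Capn5 (0.19), Myc (0.20), Runx1 (0.20), Atp6v0a1 (0.38) and Ccng2 (0.74) lost their call, given with the adjusted p. Of the genes named, Il2ra (5 of 6, up to 0.18), Ccng2 (4 of 6, up to 0.22), Atp6v0a1 (3 of 6, up to 0.12) and Dtx1 (2 of 6, up to 0.055) lost their call in some of the 6 fits with 1 array left out, given here with the highest adjusted p.

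DNMAML in DMSO lowered the same kind of targets and raised many other genes. Rag1, which cuts antigen receptor genes for recombination, fell by 2.15 (SE 0.31, adjusted p = 2.8e-04) from 5.23 ± 0.72 to 3.08 ± 0.24, a level below the median of every array, which makes the size uncertain. Myc fell by 1.40 (SE 0.21, adjusted p = 4.3e-04), Nrarp fell by 1.24 (SE 0.11, adjusted p = 5.0e-07) and Il2ra, the alpha chain of the interleukin-2 receptor, fell by 1.36 (SE 0.14, adjusted p = 9.2e-06). With 4.07 in DNMAML-DMSO, Nrarp lay within the range of the array medians, so the size of its fall may be uncertain. The largest rises were those of the chemokine receptor Ccr8, at 2.87 (SE 0.39, adjusted p = 1.5e-04), of Cpa3, a mast cell carboxypeptidase, at 2.28 (SE 0.26, adjusted p = 2.0e-05), and of Sla, an adaptor that dampens T-cell receptor signalling, at 1.92 (SE 0.25, adjusted p = 7.8e-05). Pdcd1, which encodes the inhibitory receptor PD-1, rose by 1.57 (SE 0.23, adjusted p = 3.9e-04).

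Under DNMAML 7 of the 28 Notch targets fell (Hes1, Hey1, Dtx1, Nrarp, Notch3, Il2ra and Myc) and 2 rose, the T-cell transcription factor Gata3 by 0.62 (SE 0.11, adjusted p = 0.0019) and Lztfl1 by 1.01 (SE 0.12, adjusted p = 5.5e-05). Adjusted over the list alone, 8 fell and 2 rose (camera adjusted p = 8.0e-05; 0.0013 with an estimated correlation). Notch1 was at -0.46 (SE 0.13, adjusted p = 0.066), and with the replicate block its adjusted p was 0.028. Of 55 Myc and ribosome biogenesis genes 9 fell and 0 rose, and 22 fell when adjusted over the list alone, among them Ndufaf4 (-0.82, SE 0.11), the spermidine synthase Srm (-0.78, SE 0.15), the RNA polymerase I subunit Polr1b (-0.76, SE 0.17) and the nucleolar protein Nolc1 (-0.72, SE 0.13). The list's camera p was 2.9e-19, and 0.048 with an estimated correlation. Of 27 G2/M genes 3 rose, the spindle genes Nusap1 (0.59, SE 0.14) and Tpx2 (0.57, SE 0.13) and the mitotic cyclin Ccnb2 (0.47, SE 0.11), and 9 when adjusted over the list alone (camera adjusted p = 6.9e-13; adjusted p = 0.076 with an estimated correlation). Of 23 quiescence genes 2 rose, Txnip, a regulator of glucose uptake (1.10, SE 0.14), and the cell-cycle inhibitor Cdkn1b (0.62, SE 0.13), and 2 when adjusted over the list alone (camera adjusted p = 7.1e-04; 0.0066 with an estimated correlation). Of 30 T-lineage genes 8 rose and 2 fell, and 12 and 2 when adjusted over the list alone. The rises included the T-cell receptor chain Cd247 (1.08, SE 0.18), the stem cell factor receptor Kit (1.05, SE 0.12) and Cd4 (0.97, SE 0.15), the last from 3.86 in MigR1-DMSO, near background, so its size is uncertain. The list's camera p was 1.4e-07, and 0.017 with an estimated correlation.

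DNMAML changed 386 genes, 220 higher and 166 lower, and 934 with the replicate block. The split became 179 and 178 with every probe set and 102 and 101 without DNMAML-DMSO replicate 2, so the excess of higher genes was not stable. The count was 222 without MigR1-DMSO replicate 2, 186 without MigR1-DMSO replicate 3, and 245, 203 and 235 without DNMAML-DMSO replicate 1, 2 or 3. Calls of Hes1 (2 of 6, up to 0.071), Notch3 (4 of 6, up to 0.20), Polr1b (3 of 6, up to 0.14), Nusap1 (4 of 6, up to 0.19), Tpx2 (3 of 6, up to 0.18), Ccnb2 (4 of 6, up to 0.19) and Cdkn1b (1 of 6, up to 0.075) were lost in some of the 6 fits with 1 array left out.

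GSI and DNMAML changed an overlapping group of genes, Nrarp, Hey1, Dtx1, Il2ra and Myc among them. Of the 27 genes lowered by GSI, 24 were also lowered by DNMAML, where independent lists would share 0.225, and of the 6 raised by GSI 5 were also raised (0.0662 for independent lists). Both comparisons use the MigR1-DMSO arrays. Across genes their log2 differences correlated with r of 0.61, against 0.47 in simulated unchanged groups that share their controls, with a covariance of 0.0212 against 0.0146.

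**Figure D1:**
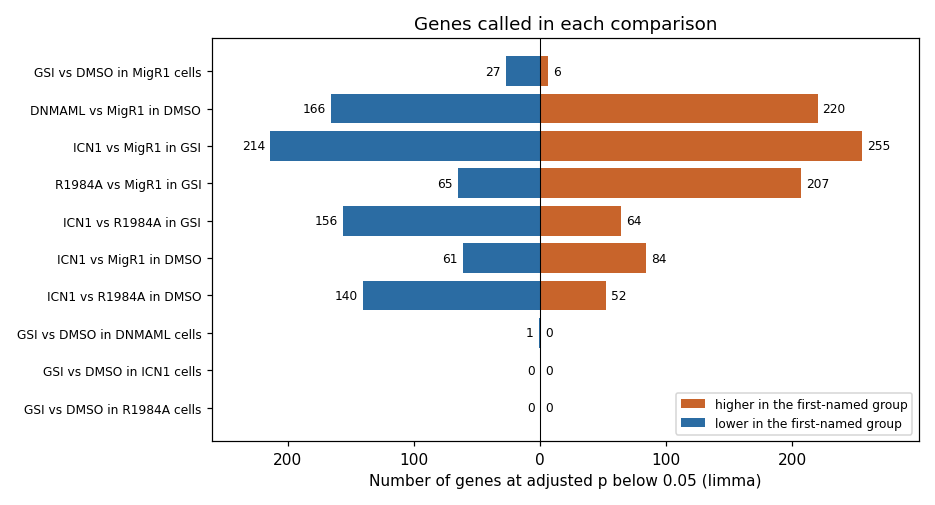
Number of genes called at an adjusted p under 0.05 by limma in each of the 10 group comparisons, with bars for genes higher and genes lower in the first-named group. The bars run from 255 higher and 214 lower genes for ICN1 against MigR1 in GSI down to 0 genes for GSI in ICN1 or R1984A cells.

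ICN1 cells kept high levels of Notch targets in GSI. Against MigR1-GSI, Nrarp rose by 2.28 (SE 0.11, adjusted p = 3.4e-12), Myc by 1.75 (SE 0.21, adjusted p = 1.0e-05), Dtx1, a ubiquitin ligase of the Notch pathway, by 1.72 (SE 0.21, adjusted p = 9.4e-06) and Hes1, a transcriptional repressor, by 1.08 (SE 0.14, adjusted p = 2.8e-05). Large rises were measured in Rag1, by 3.93 (SE 0.31, adjusted p = 2.3e-08) from 3.83 ± 0.42 to 7.75 ± 0.34, its neighbour Iftap, by 3.75 (SE 0.28, adjusted p = 1.1e-08), Tmem255a, by 3.75 (SE 0.24, adjusted p = 5.9e-10), and Serpinb8, by 3.29 (SE 0.17, adjusted p = 1.8e-11). In MigR1-GSI Rag1, Iftap (3.21) and Tmem255a (3.33) lay below the median of every array, near background, so the sizes of these rises are uncertain. Nrarp, at 4.09 in MigR1-GSI, lay within the range of the array medians, so the size of its rise may be uncertain too. The chemokine receptor Ccr8 was at -3.45 (SE 0.39, adjusted p = 4.1e-06), the thymus-homing receptor Ccr9 at -2.39 (SE 0.27, adjusted p = 4.8e-06) and Cpa3 at -2.33 (SE 0.26, adjusted p = 3.4e-06).

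Of the 28 Notch targets, 11 were higher in ICN1-GSI than in MigR1-GSI and 3 lower (Gata3, Lztfl1 and the cell-cycle kinase Cdk6), with 13 and 3 when adjusted over the list alone and a camera p of 2.0e-08 (5.4e-05 with an estimated correlation). Of the 5 paired-site targets 4 were higher (camera adjusted p = 1.8e-13; 1.4e-05 with an estimated correlation). Of the 2 dimer-independent ones 2 were higher (camera adjusted p = 1.9e-10; 1.3e-04). Of 34 Notch pathway components 3 were higher (camera adjusted p = 0.29), Notch1, Notch3 and the ligand gene Jag1 (1.16, SE 0.13). Whether the first reads the construct is open. Of 55 Myc and ribosome biogenesis genes 8 were higher and 0 lower, and 11 higher when adjusted over the list alone, among them Ndufaf4 (0.77, SE 0.11), Polr1b (0.77, SE 0.17) and Nip7, a factor of ribosome assembly (0.71, SE 0.14). That list's camera p of 6.9e-15 became an adjusted p = 0.14 with an estimated correlation. T-lineage genes went both ways, 3 higher and 9 lower of 30, and 6 and 12 when adjusted over the list alone (median -0.20, camera adjusted p = 9.1e-04 downward, adjusted p = 0.17 with an estimated correlation). Rag1 and Rag2 were among the higher ones, and Kit (-0.93, SE 0.12) and Cd4 among the lower ones, opposite to their rise under DNMAML. With 3.39 in ICN1-GSI, Cd4 lay near background, so the size of its fall is uncertain.

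Single members of other lists changed in ICN1-GSI. The cholesterol synthesis enzyme Sqle rose (1.29, SE 0.14), as did the stress-induced Nupr1 (1.66, SE 0.21), the interferon-response factor Irf9 (0.92, SE 0.18) and the cytotoxic granule gene Prf1 (1.47, SE 0.16), while the survival gene Bcl2 fell (-0.89, SE 0.11). The camera p-values of the cholesterol synthesis, amino acid stress and interferon-response lists, 0.017, 0.035 and 0.0073, became adjusted p = 0.54, 0.37 and 0.32 with an estimated correlation. The natural killer list and the p53 and apoptosis list had camera p-values of 0.41 and 0.20.

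ICN1-GSI and MigR1-GSI differed in 469 genes, 255 higher and 214 lower in ICN1-GSI. The split became 295 and 309 after a second quantile normalization, 289 and 300 with array weights, 158 and 208 without MigR1-GSI replicate 3, 154 and 197 without ICN1-GSI replicate 1, and 175 and 191 without all replicate 3 arrays, so which direction held more genes is open. Of the genes named, Cdk6 (5 of 6, up to 0.15), Ptcra (5 of 6, up to 0.16), Notch3 (2 of 6, up to 0.064) and Polr1b (2 of 6, up to 0.10) lost their call in some of the 6 fits with 1 array left out. Many of the changes were opposite to those of DNMAML in DMSO, a comparison that shares no array with this one, with r of -0.45 across genes. Of the 220 genes raised by DNMAML 107 were lower in ICN1-GSI, and of the 166 lowered 81 were higher, where independent lists would share 2.36 and 2.12; 0 genes went the same way in both.

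R1984A cells in GSI held some Notch targets above MigR1-GSI, while others were not called. Nrarp was higher by 2.03 (SE 0.11, adjusted p = 4.2e-11), Il2ra by 1.49 (SE 0.14, adjusted p = 7.3e-07), Dtx1 by 1.496 (SE 0.21, adjusted p = 9.3e-05) and Hey1 by 1.12 (SE 0.11, adjusted p = 7.3e-07). The size for Nrarp may be uncertain, with 4.09 in MigR1-GSI. Myc was at 0.61 (SE 0.21, adjusted p = 0.31), Hes1 at 0.37 (SE 0.14, adjusted p = 0.42) and Ptcra, the pre-T-cell receptor alpha chain, at -0.19 (SE 0.17, adjusted p = 0.99), none of them called. Large rises were measured in the chitinase Chit1, by 2.66 (SE 0.23, adjusted p = 2.6e-07) from 3.31, a level near background, the platelet-derived growth factor receptor Pdgfrb, by 2.54 (SE 0.16, adjusted p = 5.1e-10), and Mfsd2a, by 2.48 (SE 0.17, adjusted p = 2.4e-09). Ccr8 was at -3.53 (SE 0.39, adjusted p = 4.2e-06) and Ccr9 at -1.83 (SE 0.27, adjusted p = 2.4e-04). Ccr8 averaged 4.21 ± 1.18 in R1984A-GSI, a wide spread close to the highest array median of 4.18, so the size of its fall is uncertain.

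Of the 28 Notch targets 7 were higher in R1984A-GSI and 2 lower (Gata3 and Lztfl1), and 11 and 2 when adjusted over the list alone, with a camera p of 7.2e-09 and 3.1e-05 with an estimated correlation. Of the 5 paired-site targets Nrarp alone was called, and 3 were higher when adjusted over the list alone (camera adjusted p = 4.6e-05; 0.0019 with an estimated correlation). Both dimer-independent targets were higher (camera adjusted p = 1.3e-13; 3.1e-05). Of 55 Myc and ribosome biogenesis genes limma called 0, and 1 had an unadjusted p under 0.05, with a camera adjusted p of 0.95. Of 34 pathway components 3 were higher, Notch1, Notch3 and Jag1, with a camera p of 0.0076 (0.031 with an estimated correlation). Of 30 T-lineage genes 2 were higher and 4 lower, Kit (-0.54, SE 0.12) and Cd4, near background at 3.53 in R1984A-GSI, among the lower (camera adjusted p = 0.036; adjusted p = 0.49 with an estimated correlation). Of 23 quiescence genes 2 were higher, Btg1 (1.03, SE 0.17) and Foxp1 (0.61, SE 0.13), with a median of -0.10, a mean of 0.01 and a camera p of 0.94 downward. The cholesterol synthesis list, of which limma called 0 with 2 at an unadjusted p under 0.05, had a camera p of 0.028 and an adjusted p = 0.74 with an estimated correlation.

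R1984A-GSI and MigR1-GSI differed in 272 genes, 207 higher and 65 lower, a split that became 181 and 99 after a second quantile normalization and 403 and 287 with array weights; without R1984A-GSI replicate 3 the count was 179. Gata3 (5 of 6, up to 0.23), Cd4 (3 of 6, up to 0.060), Kit (3 of 6, up to 0.18) and Foxp1 (4 of 6, up to 0.084) lost their call in some of the 6 fits with 1 array left out. Of the 255 genes higher in ICN1-GSI, Nrarp, Dtx1 and Hey1 among them, 89 were also higher in R1984A-GSI, and of the 214 lower 53 were also lower (2.65 and 0.698 for independent lists). Across genes r was 0.58, against 0.50 in simulated unchanged groups that share the MigR1-GSI arrays, and the covariance 0.0281 against 0.0152. These simulated groups, too, were drawn without regard to the replicate number and are no exact benchmark.

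The dimerizing and the dimer-defective form were then compared directly in GSI. Targets linked to paired sites were higher with ICN1, Myc by 1.14 (SE 0.21, adjusted p = 0.0052) at 9.52 ± 0.12 against 8.38 ± 0.21, Ptcra by 0.85 (SE 0.17, adjusted p = 0.0082) at 5.05 ± 0.23 against 4.203 ± 0.36, and Hes1 by 0.71 (SE 0.14, adjusted p = 0.0082) at 5.44 ± 0.33 against 4.72 ± 0.16. Ptcra in R1984A-GSI lay close to the highest array median of 4.18, so the size of its difference may be uncertain. Of the 5 on the paired-site list 3 were called higher and 0 lower, and 4 higher when adjusted over the list alone, with a camera p of 2.4e-07 and 6.2e-04 with an estimated correlation. Nrarp was at 0.25 (SE 0.11, adjusted p = 0.46), with a 95% interval of 0.03 to 0.47, and Hes5 at 0.01. For the targets taken to be independent of dimerization the differences were 0.02 for Hey1 (95% interval -0.20 to 0.24) and -0.24 for Il2ra (95% interval -0.53 to 0.06). Limma called 0 of these, with 0 at an unadjusted p under 0.05.

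Over all 28 Notch targets, 4 were higher in ICN1-GSI than in R1984A-GSI (Hes1, Ptcra, Myc and Nfkb2, with Nfkb2 at 0.59, adjusted p = 0.028). Cdk6 was lower, at -0.58 (SE 0.11, adjusted p = 0.0055), while 23 were not called. Among the latter, Gimap5 was at -0.55 and passed with the replicate block (adjusted p = 0.0145). Its means of 2.92 in ICN1-GSI and 3.47 in R1984A-GSI lay near background. There were 4 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.55). Dtx1 differed by 0.22 (95% interval -0.20 to 0.65). Of 55 Myc and ribosome biogenesis genes 4 were higher and 0 lower, Srm (0.93, SE 0.15), Nip7 (0.62, SE 0.14), Ndufaf4 (0.58, SE 0.11) and Nolc1 (0.56, SE 0.13), and 8 higher when adjusted over the list alone (camera adjusted p = 1.3e-18; adjusted p = 0.16 with an estimated correlation). Of 27 G2/M genes the mitotic kinase Ttk alone was called, at -0.45 (camera adjusted p = 6.9e-06 downward; adjusted p = 0.47 with an estimated correlation). Of 23 quiescence genes 3 were lower, Btg1 (-0.72, SE 0.17), Txnip (-0.64, SE 0.14) and Foxp1 (-0.58, SE 0.13), with a camera p of 0.11. In the amino acid stress list Nupr1 was higher (0.95, SE 0.21), with a camera p of 4.4e-04 and an adjusted p = 0.30 with an estimated correlation.

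**Figure D2:**
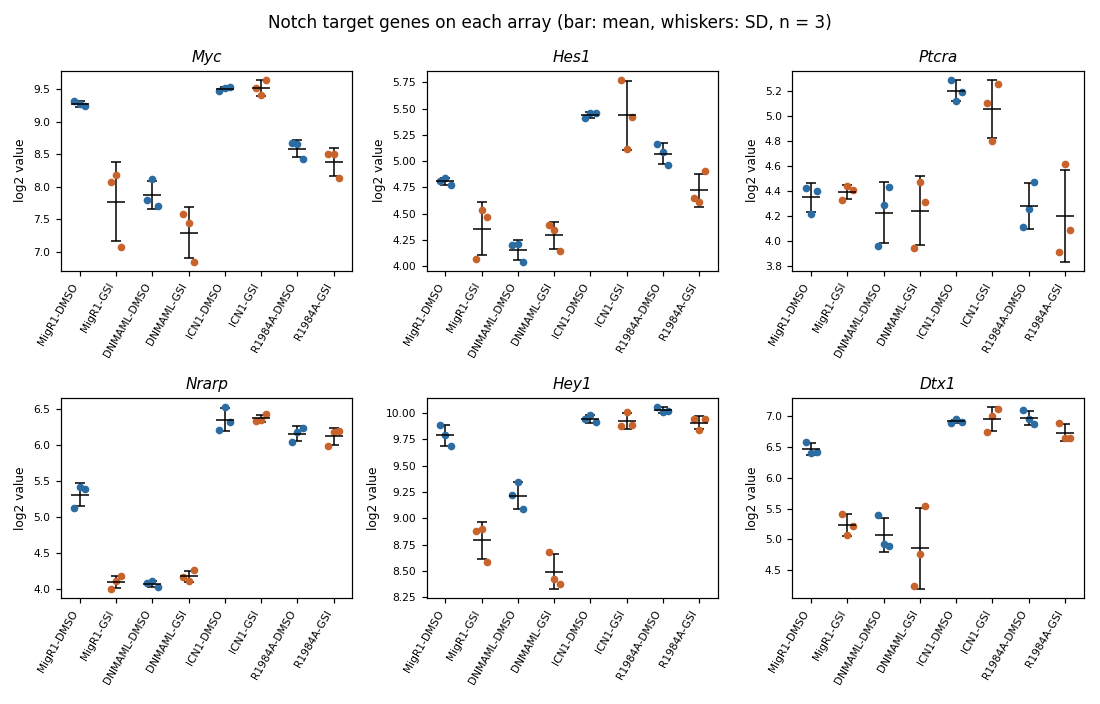
Log2 values of Myc, Hes1, Ptcra, Nrarp, Hey1 and Dtx1 on each array in the 8 groups, with blue points for DMSO, orange for GSI, a bar for the mean and whiskers for the SD (3 arrays each); each panel has its own axis. In GSI, Myc averaged 9.52 in ICN1 and 8.38 in R1984A cells, while Hey1 averaged 9.93 and 9.91.

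Large differences between both forms were measured outside the Notch target list. Iftap was higher in ICN1-GSI by 3.79 (SE 0.28, adjusted p = 1.9e-08), Rag1 by 3.27 (SE 0.31, adjusted p = 1.1e-06) and Rag2, the partner of Rag1 in recombination, by 2.59 (SE 0.21, adjusted p = 5.3e-08). These 3 genes are adjacent on chromosome 2. Tmem255a was higher by 3.52 (SE 0.24, adjusted p = 4.2e-09), the epidermal transcription factor Zfp750 by 2.75 (SE 0.15, adjusted p = 1.6e-10) and the cytokine Il10 by 1.82 (SE 0.20, adjusted p = 8.4e-06). In R1984A-GSI Iftap (3.18), Rag2 (2.53), Tmem255a (3.55) and Il10 (3.27) lay below the median of every array, so the sizes of their differences are uncertain, while Rag1 stood at 4.49. Lower in ICN1-GSI were the peptide transporter Slc15a1, at -2.15 (SE 0.34, adjusted p = 9.7e-04), Tmem273, at -2.11 (SE 0.34, adjusted p = 0.0012), the G-protein regulators Rgs1, at -1.57 (SE 0.17, adjusted p = 8.4e-06), and Rgs2, at -1.23 (SE 0.24, adjusted p = 0.0080), and the transcription factor Etv5, at -1.17 (SE 0.12, adjusted p = 6.3e-06). Of 30 T-lineage genes 2 were higher and 4 lower, and 3 and 9 when adjusted over the list alone, with a median of -0.09, a mean of 0.06 and a camera p of 0.087 downward. The lower ones were the signalling adaptor Lcp2 (-0.60, SE 0.10), Themis (-0.55, SE 0.14), which sets T-cell receptor thresholds, and the transcription factors Tox (-0.52, SE 0.10) and Ikzf1 (-0.48, SE 0.11).

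**Figure D3:**
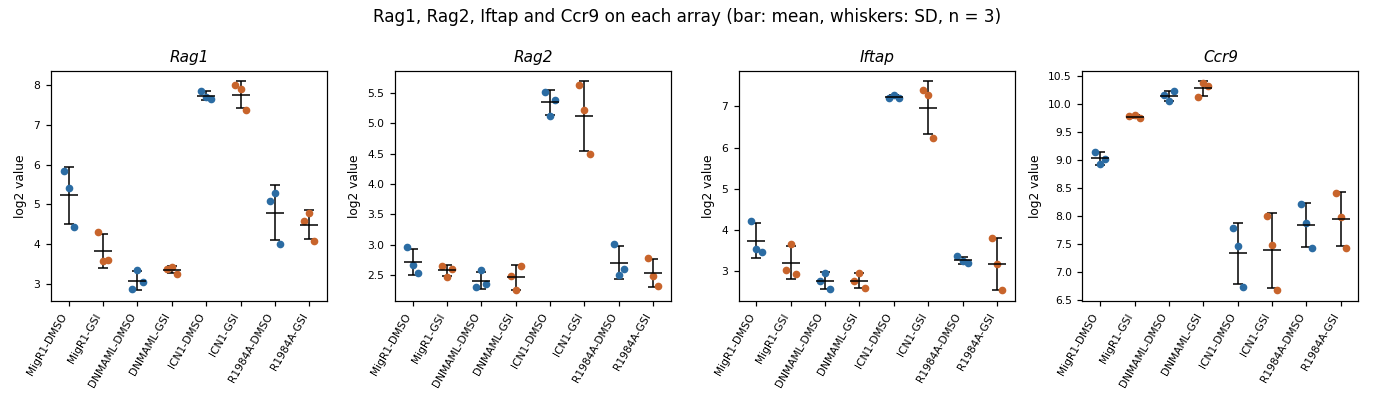
Log2 values of Rag1, Rag2, Iftap and Ccr9 on each array in the 8 groups, with blue points for DMSO, orange for GSI, a bar for the mean and whiskers for the SD (3 arrays each); each panel has its own axis. Rag1 averaged 7.73 and 7.75 in ICN1 cells, and between 3.08 and 5.23 in the other groups.

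In all, 220 genes were called between ICN1-GSI and R1984A-GSI, 64 higher and 156 lower in ICN1-GSI, a split that became 123 and 165 after a second quantile normalization, 56 and 59 without ICN1-GSI replicate 3 and 26 and 25 with only the groups compared. The count was 577 with the replicate block. It was 115 without ICN1-GSI replicate 3, 122 without R1984A-GSI replicate 2, 132 without R1984A-GSI replicate 3 and 129 without all replicate 3 arrays. Myc stayed called in each of the 6 fits with 1 array left out. Hes1 lost its call without ICN1-GSI replicate 1 (adjusted p = 0.069) or R1984A-GSI replicate 2 (0.064), and Ptcra without ICN1-GSI replicate 3 (0.069) or R1984A-GSI replicate 1 (0.068) or 3 (0.055). Cdk6 (1 of 6, up to 0.052), Nfkb2 (4 of 6, up to 0.19), Nip7 (4 of 6, up to 0.14), Ndufaf4 (2 of 6, up to 0.072), Nolc1 (5 of 6, up to 0.22), Ttk (5 of 6, up to 0.16), Btg1 (5 of 6, up to 0.20), Txnip (6 of 6, up to 0.11), Foxp1 (5 of 6, up to 0.17), Nupr1 (5 of 6, up to 0.19), Rgs2 (1 of 6, up to 0.069), Themis (5 of 6, up to 0.27) and Ikzf1 (4 of 6, up to 0.13) did so in some of these fits.

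The 24 genes that both GSI and DNMAML lowered in cells without ICN1 or R1984A were then followed in the cells that carried these constructs. In GSI, 24 were higher in ICN1 than in MigR1 cells and 13 were higher in R1984A than in MigR1 cells. The MigR1-GSI arrays also chose the set, which favours this direction. The ICN1-GSI and R1984A-GSI arrays entered that choice through the common spread estimate. Chosen on the MigR1 and DNMAML-DMSO arrays alone, the set held 10 genes, with a median difference of 0.58 between ICN1-GSI and R1984A-GSI. Of the 24, 9 were called higher with ICN1 (Serpinb8 at 1.70, Capn5 at 1.38, Deptor at 1.35, Myc at 1.14, Prag1 at 1.02, Dennd2d at 0.82, Rrp1b at 0.58, Zcchc2 at 0.56 and Afdn at 0.46) and Mfsd2a was lower, at -0.88. The median difference of the set was 0.38 (camera p = 1.9e-16, unadjusted since 1 set was tested; 8.5e-05 with an estimated correlation), and 20 of the 24 were above 0. Against MigR1-GSI, Deptor was at 1.13 in ICN1 and at -0.22 in R1984A cells, the latter not called.

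**Figure D4:**
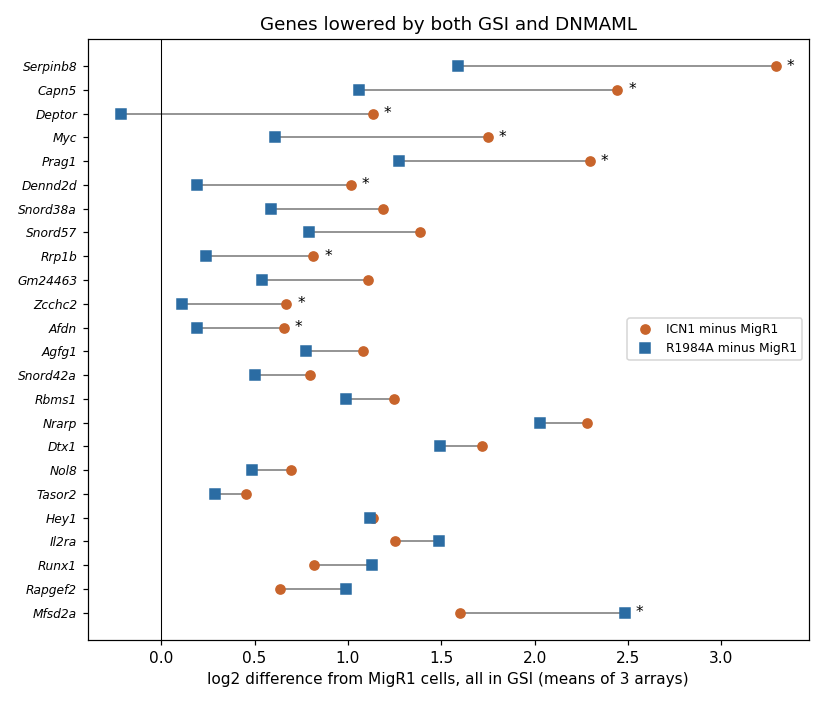
Log2 difference from MigR1 cells of the 24 genes lowered by both GSI and DNMAML, all in GSI, with circles for ICN1 and squares for R1984A (differences of means over 3 arrays) and an asterisk where ICN1 and R1984A differed at an adjusted p under 0.05. Serpinb8 lies at 3.29 and 1.59, Hey1 at 1.14 and 1.12, and Mfsd2a at 1.60 and 2.48.

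In DMSO, where the Notch signal was not blocked by GSI, ICN1 still raised some targets above MigR1. Nrarp was higher by 1.05 (SE 0.11, adjusted p = 2.8e-06), Ptcra by 0.85 (SE 0.17, adjusted p = 0.010) and Hes1 by 0.64 (SE 0.14, adjusted p = 0.026). Of 28 Notch targets 7 were higher and 1, Lztfl1, lower (9 and 4 when adjusted over the list alone; camera adjusted p = 6.0e-04, and 0.0056 with an estimated correlation). Tmem255a rose by 3.55 (SE 0.24), Iftap by 3.48 (SE 0.28), Rag2 by 2.63 (SE 0.21) and Rag1 by 2.502 (SE 0.31), the first 3 from levels near background in MigR1-DMSO. Ccr8 fell by 2.26 (SE 0.39). Of 27 interferon-response genes 2 rose, Oas1a (1.33, SE 0.25) and Irf9 (0.92, SE 0.18), and 8 when adjusted over the list alone (camera adjusted p = 5.2e-06; adjusted p = 0.090 with an estimated correlation). Of 55 Myc and ribosome biogenesis genes limma called 0, with 1 at an unadjusted p under 0.05 (camera adjusted p = 1.9e-05; adjusted p = 0.35 with an estimated correlation). Camera calls of the dimer-independent, cholesterol synthesis, amino acid stress, p53 and T-lineage lists were also lost, at adjusted p = 0.052, 0.35, 0.35, 0.075 and 0.35 with an estimated correlation. ICN1 changed 145 genes in DMSO, 84 higher and 61 lower, and 297 with the replicate block. The count was 95, 79 and 91 without MigR1-DMSO replicate 1, 2 or 3 and 80 without ICN1-DMSO replicate 3. Hes1 (6 of 6, up to 0.12), Ptcra (3 of 6, up to 0.082), Irf9 (2 of 6, up to 0.10) and Oas1a (1 of 6, up to 0.058) lost their call in some of the 6 fits. Of the genes higher in ICN1-GSI than in MigR1-GSI 74 were also higher in DMSO, and of the lower ones 56, where independent lists would share 1.07 and 0.655.

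ICN1 and R1984A differed in DMSO in many of the genes that set them apart in GSI. Myc was higher with ICN1 by 0.92 (SE 0.21, adjusted p = 0.027), Ptcra by 0.92 (SE 0.17, adjusted p = 0.0044), Iftap by 3.96 (SE 0.28), Rag1 by 2.94 (SE 0.31) and Rag2 by 2.64 (SE 0.21), with Iftap and Rag2 near background in R1984A-DMSO, while Tmem273 was at -2.37 (SE 0.34) and Rgs1 at -1.49 (SE 0.17). Ptcra, at 4.28 in R1984A-DMSO, lay close to the highest array median of 4.18, so the size of its difference may be uncertain. Of the 5 paired-site targets 2 were called higher, and 3 when adjusted over the list alone (camera adjusted p = 1.4e-06; 0.0012 with an estimated correlation). Of 23 quiescence genes 1 was higher and 1 lower, and 1 and 6 when adjusted over the list alone, with a camera p of 2.4e-04 downward (0.0054 with an estimated correlation). Camera calls of the Myc, G2/M, T-lineage and amino acid stress lists were lost, at adjusted p = 0.23, 0.62, 0.23 and 0.62 with an estimated correlation. Of the genes called in GSI, 43 higher and 92 lower ones were also called in DMSO, where independent lists would share 0.167 and 1.10. There were 192 calls in DMSO, 52 higher and 140 lower, and 456 with the replicate block, with 99 without ICN1-DMSO replicate 3 and 100 without R1984A-DMSO replicate 2. Myc lost its call whichever of the 6 arrays was left out (6 of 6, up to 0.14).

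Few or no genes were called for GSI in cells that carried DNMAML, ICN1 or R1984A. In DNMAML cells limma called 1 gene, Hey1, which fell by 0.72 (SE 0.11, adjusted p = 0.014), with 507 genes at an unadjusted p under 0.05. Its call was lost in some fits with 1 array left out (4 of 6, up to 0.28). In ICN1 cells limma called 0 genes, with 472 at an unadjusted p under 0.05, and in R1984A cells 0, with 635. All of these unadjusted counts lay below the 996.9 expected by chance, so an absent call does not show an absent change. Nrarp was at 0.11, 0.02 and -0.04 in DNMAML, ICN1 and R1984A cells, and Myc at -0.58, 0.01 and -0.21, none of them called. The dimer-independent list in DNMAML cells had a camera p of 9.1e-04 and an adjusted p = 0.058 with an estimated correlation. The Myc list had 2.3e-06 and 9.0e-04 in DNMAML and R1984A cells, which became adjusted p = 0.83 and 0.81 with an estimated correlation.

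Whether these responses differed from that of MigR1 cells was tested directly. The response of Nrarp differed in DNMAML cells by 1.32 (SE 0.15, adjusted p = 2.0e-04), where 4.07 before GSI left little room to fall, in ICN1 cells by 1.23 (SE 0.15, adjusted p = 6.6e-04) and in R1984A cells by 1.18 (SE 0.15, adjusted p = 0.0014). Hey1 differed in ICN1 cells by 0.98 (SE 0.15, adjusted p = 0.0090) and in R1984A cells by 0.88 (SE 0.15, adjusted p = 0.030), and Mfsd2a by 1.74 (SE 0.24, adjusted p = 0.0018) and 1.42 (SE 0.24, adjusted p = 0.030). In all, 1, 3 and 5 genes passed in DNMAML, ICN1 and R1984A cells, and for DNMAML 4 with the replicate block. Without all replicate 3 arrays the counts were 0, 1 and 0. With 1 array left out in each of 12 fits they ran from 1 to 3, 2 to 5 and 1 to 6, the highest without MigR1-GSI replicate 1. Hey1 (11 of 12, up to 0.15) and Mfsd2a (9 of 12, up to 0.13) lost their call for R1984A cells, Hey1 also for ICN1 cells (2 of 12, up to 0.057). For ICN1 against R1984A cells limma called 0 genes, with 460 at an unadjusted p under 0.05, below the 996.9 expected by chance.

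Markers of other cells changed in single genes. In the stroma and epithelium list Pdgfrb and Cdh1, the gene of E-cadherin, were lower under DNMAML (-0.63, SE 0.16, and -0.68, SE 0.14) and higher in ICN1-GSI (1.65, SE 0.16, and 1.14, SE 0.14) and R1984A-GSI (2.54, SE 0.16, and 0.73, SE 0.14). The list's camera p-values of 0.035 and 0.023 in the latter became adjusted p = 0.33 and 0.44 with an estimated correlation. Calls under DNMAML of Pdgfrb (6 of 6, up to 0.17) and Cdh1 (2 of 6, up to 0.070) were lost in some of the 6 fits with 1 array left out. The B-cell coactivator Pou2af1 was higher in R1984A-GSI (0.81, SE 0.15), with 12 of the 13 B-cell markers not called (camera adjusted p = 0.38). Of 29 G1/S genes, 16 myeloid and 9 erythroid or megakaryocyte markers limma called 0 between ICN1-GSI and R1984A-GSI, with 0, 0 and 1 at an unadjusted p under 0.05, and camera p-values of 0.74, 0.93 and 0.74.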

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

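The tests of the GSI response and of the lists were planned. Of the tests of explanations, all but those of a lower yield of all small RNAs and of a shift of all genes of the same abundance were chosen only after the result was seen.

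The response to GSI differed between constructs for single genes, by a direct test of the difference. Nrarp responded less than in MigR1 cells by 1.32 in DNMAML, 1.23 in ICN1 and 1.18 in R1984A cells. In DNMAML-DMSO it was already at 4.07, the level of MigR1-GSI (4.09), and could hardly fall further, so the first value shows no lost response. Mfsd2a did so by 1.74 in ICN1 and 1.42 in R1984A cells, and Hey1 by 0.98 and 0.88. In R1984A cells Agfg1 differed by 0.77 and Snord38a by 1.25. Snord38a lies outside the rule for genes named and was chosen after its values were seen. Agfg1 lost its call in each of 12 fits with 1 array left out, with an adjusted p of up to 0.15. The list medians of the difference in DNMAML, ICN1 and R1984A cells were 0.14, 0.13 and 0.044 for all Notch targets, 0.59, 0.44 and 0.10 for paired-site targets and 0.53, 0.81 and 0.85 for Hey1 and Il2ra, the targets taken to be independent of dimerization.

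For the interactions, 100 of the possible regroupings of the 12 arrays were drawn, the real one included. As many genes as the real 1, 3, 5 and 0 were called in 17 of them for DNMAML, 11 for ICN1 and 14 for R1984A against MigR1, and 100 for ICN1 against R1984A. Of the regroupings other than the real one that reached the first 3 counts, 16 of 16, 10 of 10 and 12 of 13 took unequal shares of a construct in DMSO and in GSI, which carries the construct's own effect into the response, so these shares neither exclude chance nor show it. The highest counts in the other regroupings were 212, 227, 1357 and 8, of which 212, 227 and 8 came from unequal shares. With equal shares the highest counts were 0, 0, 1357 and 1. Only the 1357 thus points to a structure of the samples apart from the constructs. The one with 1357, for R1984A, took equal shares and put both replicate 3 arrays in GSI into one group and both in DMSO into the other; with the replicate block the real count was 12.

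For the comparisons of groups, the 6 arrays make 10 splits, which are too few for a share under 0.05. The real count and the highest of the other splits were 33 and 0 for GSI in MigR1 cells, 386 and 0 for DNMAML, 469 and 5 for ICN1 and 272 and 54 for R1984A against MigR1 in GSI, 220 and 0 for ICN1 against R1984A in GSI, 145 and 0 for ICN1 against MigR1 and 192 and 0 for ICN1 against R1984A in DMSO. In each of these 7, 1 split, the real one, gave as many genes. All splits but the real one mix arrays of both groups, which moves any group difference into the spread. Low counts in them were thus largely fixed in advance and lend the real counts no support. For GSI in DNMAML cells 2 of 10 splits gave as many as the real 1, with 1 the highest other, and for GSI in ICN1 and in R1984A cells 10 of 10 gave as many as the real 0, with 1 the highest other.

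Probe sets with no or several gene symbols entered no comparison of genes. Tested the same way, 6 of them were called for GSI in MigR1 cells, 67 for DNMAML, 104 for ICN1 and 79 for R1984A against MigR1 in GSI, and 29 for ICN1 against R1984A in GSI.

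Most small nucleolar RNA genes, which guide the modification of ribosomal RNA and form no list tested here, had lower estimates with GSI in MigR1 cells and under DNMAML. Of 55, 50 were below 0 with GSI in MigR1 cells (median -0.50, 3 called lower) and 52 under DNMAML (median -0.68, 21 called lower), while the median was 0.47 in ICN1-GSI and 0.31 in R1984A-GSI against MigR1-GSI. A lower yield of all small RNAs, whatever their length, is argued against by the 5 other structured small RNA genes above the median probe set. Their median was 0.10 under DNMAML, while 6 near background could hardly fall. The lengths of the 5 were not set beside those of the small nucleolar RNAs, so the test cannot decide on a loss limited to shorter RNAs. Probes that read the host transcripts are argued against, as a general cause, by the 26 host genes found, with a median of -0.039. For 2 of them, Wdr43 (-0.54) and Ipo7 (-0.41), which were called lower, it stays open. The median does not set each small nucleolar RNA beside its own host, and hosts outside the 26 were not tested, so it also stays open for single small nucleolar RNAs. After the values were seen the first test was limited to these 5, and Rnu3a, the U3 small nucleolar RNA (0.84, adjusted p = 0.17), which is not among the 55, was left out. What stays open is a loss limited to shorter RNAs, the authors' normalization, whose steps are not given, and a biological explanation. As a hypothesis, the Notch signal may maintain these RNAs.

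Iftap, Rag2 and Rag1 lie next to each other and were higher in ICN1 than in R1984A cells. A gain of the chromosome stretch that reaches beyond the 3 genes is argued against by the 10 neighbouring genes, with a median of 0.014. The expression levels of these neighbours were not examined. A gain limited to the 3 genes would leave the neighbours unchanged, so it stays open. An admixture of Rag-positive thymocytes is argued against by Cd4, Cd8a, Cd8b1 and Dntt, with a median of -0.082 and ICN1-GSI means between 2.92 and 3.92. A trait of the transduced population alone stays open. Of the 3 genes 1, Rag1, was called lower under DNMAML in cells without ICN1. Iftap, at -0.97 (limma adjusted p = 0.087), and Rag2, at -0.31 (adjusted p = 0.71), were not called under DNMAML. Their levels in MigR1-DMSO, 3.75 and 2.72, lay near background, which limits what these 2 values can show. Each construct was also compared in cells that may differ in more than the construct. That the stretch responds to dimerizing Notch is an untested hypothesis.

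The Myc and ribosome biogenesis list was lower under DNMAML (median -0.34) and higher in ICN1-GSI (median 0.27). A shift of all genes of the same abundance is argued against by 10000 lists matched for abundance, among which the DNMAML median stood at percentile 0 (95% of the lists between -0.03 and 0.08). The array axis that sets replicate 3 apart is argued against by the differences within each replicate number, which were -0.35, -0.32 and -0.35 under DNMAML and 0.23, 0.15 and 0.39 in ICN1-GSI, so that 0 of 6 went the other way. With an estimated correlation the list passed under DNMAML (0.048) and not in ICN1-GSI (0.14), so a shift shared by co-regulated genes may account for the latter. That lower Myc lowers these genes is a hypothesis, since Myc was not changed alone.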

How the results depend on the processing

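Leaving out all replicate 3 arrays was chosen after the data were seen; the other alternatives were not. Direction was followed only for the named gene values and for the median of the set lowered by GSI and DNMAML. None of the called ones among them reversed under any alternative run. For named genes no reversal was possible with the replicate block, every probe set, dim genes left out, the trend or only the groups compared. These settings leave a gene's log2 difference unchanged by construction. Leaving out arrays could not reverse a gene whose 3 arrays of one group all lay above the 3 of the other. Other probe sets of the named genes were not followed. For lists and for other called genes direction was not followed, and the larger direction of the calls between ICN1-GSI and MigR1-GSI did change, as given above. Counts of genes are given where they moved by over 1.5 times; the cause was not tested, except that fits on fewer arrays have less power by construction.

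With the replicate block, GSI in MigR1 cells gave 82 genes, DNMAML 934, ICN1 and R1984A against MigR1 in GSI 960 and 496, ICN1 against R1984A 577 in GSI and 456 in DMSO, ICN1 against MigR1 in DMSO 297, GSI in ICN1 cells 1, and the differences in GSI response of DNMAML, ICN1 and R1984A from MigR1 cells 4, 7 and 12. All genes called without the block were also called with it, and of 352 named gene values 5 passed only with it and 0 were lost. Array weights gave 51 for GSI in MigR1 cells, 834 for DNMAML, 690 for R1984A against MigR1 in GSI, 739 and 384 for ICN1 against R1984A in GSI and DMSO, 316 for ICN1 against MigR1 in DMSO, and 2, 8 and 16 for the response differences. An intensity trend with robust eBayes gave 2 for the response of DNMAML cells, and every probe set 3 for that of R1984A cells.

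With only the groups compared, counts were 4 for GSI in MigR1 cells, 167 and 96 for ICN1 and R1984A against MigR1 in GSI, 51 for ICN1 against R1984A in GSI, 0 for GSI in DNMAML cells and 0 for the response of R1984A cells. Without all replicate 3 arrays they were 17 for GSI in MigR1 cells, 129 for ICN1 against R1984A in GSI, and 0, 1 and 0 for the responses of DNMAML, ICN1 and R1984A cells. Between ICN1-GSI and R1984A-GSI, Hes1 and Ptcra missed the threshold in both of these settings, at adjusted p = 0.21 and 0.16 with only the groups compared and 0.057 and 0.21 without replicate 3, and Ptcra also with array weights (0.086). Other named genes missed it too, among them Tox in both settings (0.20 and 0.10), and Lcp2 (0.10) and Slc15a1 (0.12) with only the groups compared.

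With 1 array left out in turn, counts ran from 15 to 21 for GSI in MigR1 cells, 186 to 291 for DNMAML, 351 to 411 and 179 to 244 for ICN1 and R1984A against MigR1 in GSI, 115 to 184 and 99 to 145 for ICN1 against R1984A in GSI and DMSO, 79 to 105 for ICN1 against MigR1 in DMSO, 0 to 2 for GSI in DNMAML cells, and 1 to 3, 2 to 5 and 1 to 6 for the responses of DNMAML, ICN1 and R1984A cells. For GSI in ICN1 and in R1984A cells, and for the difference between their responses, limma called 0 in each of these fits. With all arrays 472, 635 and 460 genes had an unadjusted p under 0.05, each below the 996.9 expected by chance. Of 2160 named gene values 302 were lost and 4 gained. The median of the set lowered by GSI and DNMAML ran from 0.28 to 0.56 with 1 array left out and from 0.25 to 0.69 under the others, which set the members anew, and it passed in all of them. Of the named gene values 27 were lost with every probe set, 7 with a second quantile normalization, 3 with the trend, 3 with array weights, 82 with only the groups compared and 59 without replicate 3. Outside ICN1 cells Rag2, Iftap and Tmem255a averaged at most 2.72, 3.75 and 3.68, below the median of every array, and so did Rag1 in MigR1-GSI (3.83) and DNMAML cells (3.08 and 3.35), so signal near background limits their differences.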

Other observations

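The test in this part was chosen only after the result was seen.

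Some genes were higher under DNMAML and lower with both forms of Notch in GSI, of which 39 were called in all 3 comparisons. Ccr8, a chemokine receptor of regulatory and type 2 helper T cells, was at 2.87 under DNMAML, -3.45 in ICN1-GSI and -3.53 in R1984A-GSI, and Cpa3 at 2.28, -2.33 and -1.47. With an SD of 1.18 for Ccr8 in R1984A-GSI, the size of its fall there is uncertain. Aff3, a transcriptional regulator, was at 1.68, -1.37 and -1.19, and Bhlhe41, a repressor of the clock, at 1.46, -1.44 and -1.47. Of the 220 genes raised by DNMAML 41 were lower in R1984A-GSI than in MigR1-GSI, and of the 166 lowered 30 were higher, where independent lists would share 0.717 and 1.72; 1 gene went the same way in both.

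Some genes rose more with R1984A than with ICN1. Myo1d, an unconventional myosin, was at 2.10 in R1984A-GSI against MigR1-GSI and differed between ICN1-GSI and R1984A-GSI by -1.47 (SE 0.25, adjusted p = 0.0021). Mas1, a receptor of the angiotensin system, was at 2.08 from a level near background in MigR1-GSI and differed by -1.34 (SE 0.22, adjusted p = 0.0012), and Tmem273 was at 1.80 and differed by -2.11 (SE 0.34, adjusted p = 0.0012).

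Called genes lay next to each other more often than when the calls were shuffled over all genes. Between ICN1-GSI and R1984A-GSI, 10 pairs of neighbours were called in the same direction. In 1000 such shuffles the mean was 1.38 and the highest value 7, and 0 had as many. The shuffles were not matched for expression level, so they cannot show an excess over genes of the same level. Besides Iftap, Rag2 and Rag1 the pairs included Zfp78 and Zfp28 (1.19 and 1.00), Mtfp1 and Sec14l2 (0.99 and 1.65), Pprc1 and Nolc1 (0.62 and 0.56) and Etv6 and Bcl2l14 (-0.70 and -0.68), chosen after their values were seen. The counts were 19 under DNMAML, 26 in ICN1-GSI and 15 in R1984A-GSI against MigR1-GSI, and 0 for GSI in MigR1 cells. A hypothesis is that neighbouring genes change together because they may share regulatory elements; probes that read through into a neighbour were not tested.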
